A study of Rattus norvegicus with 20 samples.

How the data were processed

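Gene expression was measured in peripheral blood mononuclear cells (PBMCs) of 4 healthy Brown Norway (BN) rats, 180 days old, after culture with plasma of other rats. The approach uses cells of a healthy animal as a detector, so that a difference between cultures of the same cells reflects what the added plasma contained. Each of the 4 responder donors was cultured with 5 plasmas, which gave 5 groups of 4 arrays and 20 arrays in all. The plasmas were the responder's own (autologous BN), that of 30-day-old DR rats (a BioBreeding strain without the lymphopenia mutation, in which diabetes can be induced) on a normal diet (DR ND), of DR rats weaned at day 20 onto a hydrolysed casein diet (DR HCD), of DR rats on the normal diet given bacitracin and streptomycin in the drinking water (DR B/S), and of 30-day-old Fischer control rats on the normal diet (F+/+ ND). The groups and the responder donor were taken from the sample titles. The descriptions of the 4 autologous samples all name the first responder, and their titles, which name 4 different responders, were followed. The labels disagree about the culture: the design text gives 20% plasma for 6 h and the treatment protocol gives 40% plasma for 9 h, so the concentration and time are uncertain. Wells held 500000 cells in 500 µl. The labels do not say whether a plasma came from 1 rat or from a pool, so the p-values measure the spread between responder cultures and not between plasma donors.

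RNA was amplified and labelled for an Affymetrix 3' expression array, per the labels' protocols. The authors deposited 1 value per probe set and array on a log2 scale, as judged from the range of the values, 1.29 to 14.3. Partek is the only program named in the submitters' processing notes. The background correction, the normalization, the summary method and the genome build were not given in the sources used here. The arrays' medians lay close together, so the values were used as deposited, with no further scaling. The table held 31099 probe sets and 0 missing values. The 57 control probe sets were left out of the tests. Of the other 31042, 20826 had 1 gene symbol in the platform annotation, 436 had several and 9780 were not listed there. Genes were named only from probe sets with 1 symbol, and 20758 of these symbols were matched to a current gene record. No genome coordinates were used. For arrays of this kind the number of arrays limits the precision.

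The tests used limma 3.58.1 in R 4.3.3. Probe sets whose mean over the 20 arrays was at or above the 40th percentile (log2 4.13) were kept, which left 18625 probe sets and 10162 named genes. A linear model with 5 group means was fitted to all 20 arrays, which share an estimate of the spread with 15 residual degrees of freedom, and tested with empirical Bayes moderation, two-sided. The p-values were adjusted by the method of Benjamini and Hochberg over the 18625 probe sets within each of 7 comparisons, and a probe set was called at an adjusted p under 0.05 with no minimum fold change. The comparisons set DR HCD, DR B/S, F+/+ ND and autologous BN plasma against DR ND plasma, and DR HCD, DR B/S and F+/+ ND against each other. The same model with the responder donor as a fixed block (12 residual degrees of freedom) was planned as an alternative. It leaves each log2 fold change as it is in this balanced design and changes its standard error (SE) and p. The design, the gene lists, the rule for the genes named and most alternatives were fixed before the data were examined.

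The pairing comes from the labels, which give the same 4 responder animals in every group. After the group means were removed, arrays of the same donor correlated with a mean r of 0.51 across probe sets and arrays of different donors with a mean r of -0.17. Of the 40 pairs of arrays from the same donor 33 had r over 0.1. The exceptions were pairs of donor 3, whose median r was 0.06 with a range from -0.16 to 0.39. Of the 20 arrays 17 correlated best with their own donor. The other 3 were of donor 3: the autologous array had a mean r of 0.55 with donor 4 and 0.04 with its own donor, the DR B/S array 0.31 with donor 1 and 0.15 with its own, and the DR HCD array 0.27 with donor 2 and -0.06 with its own. The donor numbers were kept as labelled. Because the pairing is known from the labels, values with the donor as a block are printed where they change a call or move a count by over 1.5 times.

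For each comparison with DR ND plasma the genes named are the 10 largest rises and 10 largest falls among called genes with the same sign in all 4 donors, up to 3 further called members of each gene list, and a panel of 10 inflammatory genes whether or not they were called, of which 5 were tested. Where under 10 genes were called, the places were filled from the calls with the donor as a block and then by the smallest unadjusted p, and the text says so. For the comparisons among the other plasmas the 5 largest rises and falls are named. Each gene was represented by its tested probe set with the highest mean. The 27 gene lists, 18 of cell processes and 9 of cell types, were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 24 lists with at least 5 tested genes. The other 3 lists, of neutrophils, dendritic cells and plasma cells, are only described.

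The alternatives were the donor as a fixed or random block, only the arrays of the 2 groups compared, no filter or a filter at the 60th percentile, quantile normalization, centring of the arrays on their medians, a mean-variance trend with robust moderation, array weights, an unmoderated linear model, a minimum of 1.5-fold, 1 probe set per gene, and leaving out each donor and each array in turn. Similarity between comparisons was described by the correlation and covariance of their log2 fold changes and by shared calls. Because these comparisons share the DR ND arrays, the values were set beside 100 simulations of unchanged groups and beside the 6 ways of giving each comparison 2 of the 4 DR ND arrays.

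The model was tested on data simulated from the 18625 probe sets for the comparison of DR B/S with DR ND plasma, with 50 probe sets changed at each fold size. Without the block it recovered 0% of the changes of 1.25-fold, 30% of those of 1.5-fold, 96% of those of 2-fold and 100% of those of 3-fold. With the block it recovered 24%, 88%, 100% and 100%, and 5 unchanged probe sets were among its calls. The simulated donor differences were additive, and the noise was normal, independent between probe sets and of the blocked fit's spread. The blocked model was therefore right by construction, which the real arrays, such as those of donor 3, need not follow. These shares describe that setting and may not hold for the real arrays. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.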

Results

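The data were 20 Affymetrix arrays of PBMCs from 4 BN rats, each cultured with 5 plasmas. A mononuclear cell preparation holds lymphocytes and monocytes and can carry over platelets, red cells and granulocytes. The arrays had similar distributions: the mean of the array medians was 4.70 ± 0.04 (SD, n = 4, log2) with DR ND plasma and lay between 4.67 and 4.71 in the other groups. The 3' minus 5' difference of the beta-actin probe sets, a measure of RNA integrity, was 1.36 ± 0.16 (SD, n = 4, log2) with DR ND plasma and between 1.34 and 1.37 on average with the others. That of the GAPDH probe sets was less even, with means of 0.0913 with DR ND, 0.103 with autologous, 0.0509 with F+/+, -0.0227 with DR HCD and -0.0290 with DR B/S plasma, and SDs of 0.0451 to 0.133. The responder donor accounted for a median of 44.6% of a probe set's sum of squares and the plasma for 21%. Groups without any difference also take up a share, which was not subtracted. With 5 plasma groups in 20 arrays, the 21% therefore does not show an effect of the plasma.

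The comparison of DR B/S with DR ND plasma asked whether antibiotics given to the plasma donors changed what their plasma induced. Of the 12 tested genes of the monocyte and macrophage list 3 rose with DR B/S plasma. Cd14, the co-receptor for bacterial lipopolysaccharide, rose 2.71-fold (log2 1.44 ± 0.22 SE, n = 4 arrays per group), Mpeg1, which encodes a pore-forming protein of macrophages, rose 2.46-fold (log2 SE 0.20), and Csf1r, the receptor for macrophage colony-stimulating factor, rose 1.74-fold (log2 0.80 ± 0.13). Among the named genes, each taken by 1 probe set, the largest rises were those of Fn1, which encodes the matrix protein fibronectin, at 3.88-fold (log2 1.96 ± 0.24), the chemokine receptor gene Ccr1 at 3.66-fold (log2 1.87 ± 0.20) and Tgfbi, a secreted matrix protein induced by TGF-beta, at 3.38-fold (log2 1.76 ± 0.15). Vcan, which encodes the proteoglycan versican, rose 2.62-fold, and its other probe sets rose by log2 1.37 and 2.37. Each of these rises was seen in 4 of 4 donors.

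The other named genes that rose with DR B/S plasma were Gpnmb, a membrane glycoprotein gene (2.66-fold), the C-type lectin gene Clec4a3 (2.45-fold), Lgals3, which encodes galectin-3 (2.31-fold), Ier3, a stress-induced early gene (1.93-fold), and Nqo1, a quinone reductase gene (1.76-fold), with SEs of 0.14 to 0.22 on the log2 scale. In limma 20 of the 18625 probe sets, of 13 genes, passed at a Benjamini-Hochberg adjusted p under 0.05, 20 higher and 0 lower. The adjusted p was 1.6e-06 for Tgfbi, 4.0e-05 for Ccr1, 0.00019 for Fn1, 0.0025 for Cd14 and 0.0167 for Ier3. The panel genes Il1b (1.19-fold), Il1rn (0.968-fold), Tnf (0.980-fold), Nfkbia (1.11-fold) and Mx1 (1.02-fold) did not pass (adjusted p = 1 for each). With the donor as a block 82 probe sets passed, 79 higher and 3 lower. The additional genes, named by the same rule after the result was seen, included Akr1b8, an aldo-keto reductase gene (1.99-fold, blocked adjusted p = 0.0082), the lysozyme gene Lyz2 (1.95-fold, 0.0013), Ubd, which encodes a ubiquitin-like protein (1.84-fold, 8.3e-05), and the tetraspanin gene Cd63 (1.68-fold, 0.00037), while the linker histone gene H1f2 was lower (0.661-fold, 9.6e-05). Several of the genes were dim, which limits the precision of their fold changes. Ccr1, Clec4a3 and Ier3 averaged 3.69, 3.85 and 3.9 with DR ND plasma, below the filter at 4.13 on the mean of all arrays, and Tgfbi 4.38, near it, and 9 of the 20 calls held with the filter at the 60th percentile. The count of 20 came down to 7 and 6 without donors 3 and 4, to 11 without the DR B/S array of donor 3, 10 without that of donor 4 and 11 without the DR ND array of donor 2. The blocked count of 82 came down to 44, 39 and 38 without donors 1, 2 and 4, to 53 and 48 without the DR B/S arrays of donors 2 and 3 and to 41 and 43 without the DR ND arrays of donors 1 and 2.

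**Figure D1:**
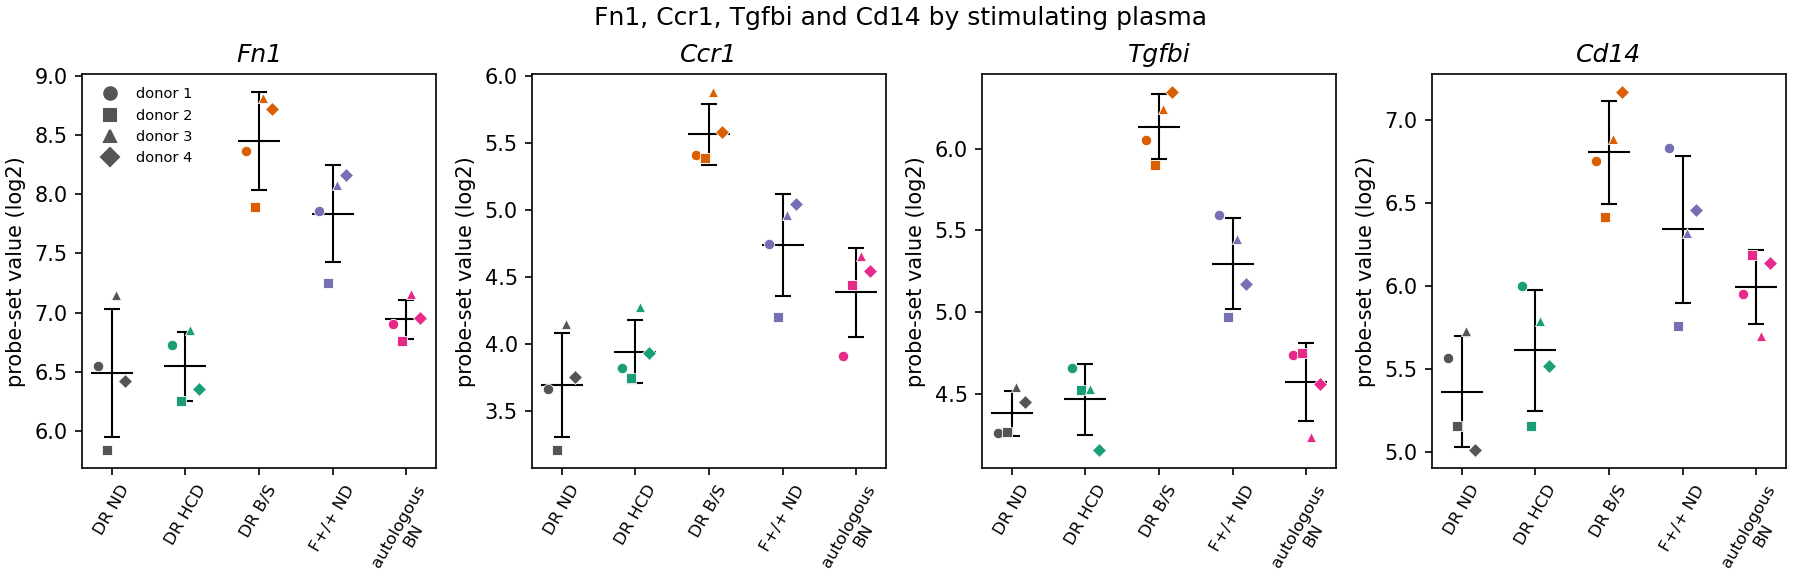
Probe-set values (log2) of Fn1, Ccr1, Tgfbi and Cd14 by stimulating plasma (points, 20 arrays with 1 shape per donor; bars, group mean and SD, n = 4). The mean of Fn1 was 6.49 with DR ND, 6.55 with DR HCD, 8.45 with DR B/S, 7.84 with F+/+ ND and 6.94 with autologous plasma.

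Of the 24 lists tested, 6 were higher with DR B/S plasma by limma's camera. Of the 12 tested monocyte and macrophage genes 3 rose (Cd14, Mpeg1 and Csf1r) and 9 did not pass, with 4 adjusted over the list alone, and 4 rose with the block, which added Lyz2 (6 adjusted over the list alone). The list's median log2 change was 0.30 (adjusted p = 6.9e-11, and adjusted p = 0.027 with an estimated correlation, 0.073 with an estimated correlation and the block). Within this list Cybb, a subunit of the phagocyte oxidase, and Fcgr3a, an Fc receptor, were nearly level, with log2 changes of -0.01 and 0.02. The unfolded protein and amino acid stress list, with 15 of 17 members above 0 and a median of 0.17 (adjusted p = 6.8e-05, but adjusted p = 0.29 with an estimated correlation and 0.073 with the block too), had 0 members past the threshold in either direction. With the block 2 rose, the chaperone gene Hspa5 (log2 0.34 ± 0.07) and Creld2 (log2 0.46 ± 0.09), with 7 adjusted over the list alone. The lists of NF-kappaB targets (19 tested, Ier3 rose), hypoxia and glycolysis (16 tested, 0 rose), sterol and fatty acid synthesis under SREBP (20 tested, 0 rose) and oxidative stress under NRF2 (11 tested, Nqo1 rose) had medians of 0.15, 0.16, 0.13 and 0.12 (adjusted p = 0.0034 for each). With an estimated correlation these 5 lists had adjusted p from 0.23 to 0.50 without the block and from 0.073 to 0.21 with it. In the list of fatty acid oxidation genes under PPAR, which was not called (adjusted p = 0.079), the lipid droplet gene Plin2 (log2 0.49 ± 0.11) and the fatty acid binding protein gene Fabp5 (log2 0.61 ± 0.11) rose with the block. The platelet list had a median of 0.04 while its test pointed lower against the other genes (adjusted p = 0.92). The neutrophil genes S100a8 and S100a9, too few to test as a list, both had a log2 change of 0.10.

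The comparison of DR HCD with DR ND plasma asked whether the hydrolysed casein diet of the plasma donors changed what their plasma induced. No gene passed. By limma 0 of 18625 probe sets passed without the block and 0 with it, with 61 and 420 at an unadjusted p under 0.05 where 931 were expected by chance, and the smallest adjusted p was 1. Both counts lay below 931, so the p-values were not spread as for independent unchanged probe sets. Without the block the donor differences stay in the spread, here and in the other comparisons, which makes that fit less sensitive. The lack of calls therefore does not show that the diet had no effect. With no gene called, the named places were filled by the smallest unadjusted p. Among them were Il23a, a cytokine subunit gene (0.801-fold, log2 -0.32 ± 0.12 SE, n = 4 arrays per group), Sqle, which encodes squalene epoxidase of sterol synthesis (0.786-fold), Jchain, which encodes the joining chain of secreted antibodies (0.709-fold, with its other probe set at log2 0.02), Tspyl4 (0.723-fold), Coq2 of ubiquinone synthesis (0.751-fold), Hexim2 (1.22-fold) and Capn15 (1.29-fold), each with an adjusted p of 1. The 20 genes taken in this way lay between 0.709-fold and 1.29-fold. Of the panel, Il1b, which encodes interleukin-1 beta, was 1.37-fold (log2 0.45 ± 0.25, higher in 4 of 4 donors, adjusted p = 1), and Il1rn, Tnf, Nfkbia and Mx1 lay between 0.955-fold and 1.02-fold. No list passed: 0 of 24 by camera, with medians from -0.05 to 0.08 and a smallest adjusted p of 0.18, and 0 members passed adjusted over the list alone (1 with the block). Cd14 averaged 5.61 ± 0.36 (SD, n = 4, log2) with DR HCD and 5.36 ± 0.34 with DR ND plasma.

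The comparison of F+/+ ND with DR ND plasma asked how plasma of the control strain differed from that of the diabetes-inducible strain at the same age and diet. Tgfbi rose 1.89-fold with F+/+ plasma (log2 0.92 ± 0.15 SE, n = 4 arrays per group, limma Benjamini-Hochberg adjusted p = 0.039), in 4 of 4 donors. Only 2 of the 18625 probe sets passed. They were Tgfbi and a probe set of Vcan, named after its values were seen, which rose by log2 1.72 ± 0.24 (adjusted p = 0.0060), while the other Vcan probe sets, at log2 0.79 and 0.64, did not pass. With the donor as a block 18 probe sets passed, 17 higher and 1 lower, and the remaining named places were filled from them. Higher with the block were Fn1 (2.54-fold, blocked adjusted p = 9.1e-06), Ccr1 (2.06-fold, 0.00018), Clec4a3 (1.97-fold, 0.0011), Cd14 (1.97-fold, 0.0278), Gpnmb (1.78-fold, 0.0154), Lyz2 (1.74-fold, 0.0304), Rasd1, a small GTPase gene induced by glucocorticoids (1.63-fold, 0.0315), Ier3 (1.47-fold, 0.0047) and Ninj1, a cell adhesion gene (1.38-fold, 0.0315). Abcg1, a cholesterol exporter, was lower (0.668-fold, 0.0315), although its other probe set was at log2 -0.15. The falls filled by unadjusted p, such as Mylip (0.724-fold, blocked adjusted p = 0.18) and Slc9a5 (0.764-fold, 0.35), did not pass, nor did Il1b (1.60-fold, adjusted p = 1, 0.76 with the block), Il1rn (1.04-fold), Tnf (0.940-fold), Nfkbia (1.07-fold) or Mx1 (1.06-fold). The call of Tgfbi was lost under quantile normalization (adjusted p = 0.077) and median centring (0.116) and when any donor was left out (0.086 to 0.86). With the stricter filter and with the unmoderated linear model 0 probe sets passed, and with array weights 18. Without the block 0 probe sets passed when donor 1, 3 or 4, the DR ND array of donor 2 or the F+/+ array of donor 3 or 4 was left out. The count was 1 when the DR ND array of donor 1 or 4, the F+/+ array of donor 1 or the DR HCD array of donor 3 was left out, and 5 without the F+/+ array of donor 2. With the block 11 and 7 passed without donors 1 and 4 and 10, 9 and 11 without the DR ND array of donor 4 and the F+/+ arrays of donors 1 and 4.

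By camera 9 of 24 lists differed with F+/+ plasma, 6 higher and 3 lower. Of the 12 monocyte and macrophage genes 0 passed over all probe sets, 4 rose adjusted over the list alone and 2 rose with the block (Cd14 and Lyz2, 5 adjusted over the list alone). The list's median was 0.18 (adjusted p = 2.2e-13, 0.011 with an estimated correlation and 0.042 with the block too). The glucocorticoid list had 10 of 11 members above 0, among them Ddit4 (log2 0.43 ± 0.09 blocked SE), Fkbp5 (0.39 ± 0.08) and Klf9 (0.38 ± 0.10), none of which passed in either fit. Its median was 0.14 (adjusted p = 2.4e-05, but adjusted p = 0.15 with an estimated correlation and 0.0078 with the block too). The lists of NF-kappaB targets, SREBP, NRF2 and unfolded protein stress were higher with medians of 0.08, 0.11, 0.09 and 0.06 (adjusted p = 0.0036 to 0.0061), and with an estimated correlation their adjusted p were 0.15 to 0.38. MHC class II presentation (median -0.05), proliferation (median -0.02) and cholesterol efflux under LXR were lower (adjusted p = 0.047 for each), with adjusted p of 0.62, 0.15 and 0.33 with an estimated correlation. The LXR list had a median of 0.00 and a mean of -0.10, since Abcg1 and Mylip were lower while Apoe, at log2 0.22, was higher and the others were near 0, so its median and its test differed in sign.

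The comparison of autologous with DR ND plasma gives the baseline of cells in their own plasma, from which the DR ND plasma donors differed in strain and age at once. Ciita, the master regulator of MHC class II genes, was 2.07-fold lower with autologous plasma (log2 -1.05 ± 0.14 SE, n = 4 arrays per group), while its other probe set, at log2 -0.39, passed only with the donor as a block. Rab27b, a small GTPase gene of granule secretion, rose 2.43-fold (log2 1.28 ± 0.25), Rasd1 rose 2.24-fold (log2 1.16 ± 0.14), Ubd rose 2.22-fold (log2 1.15 ± 0.21), and the interferon-inducible GTPase genes Gbp4 and Gbp7 rose 2.16-fold and 1.90-fold. Snap23, which encodes a membrane fusion protein, rose 1.89-fold, the cyclic AMP-responsive repressor gene Crem 1.93-fold, the lysosomal genes Manba and Laptm4b 1.83-fold and 1.75-fold, and C3h15orf48 2.04-fold. Each had the same sign in 4 of 4 donors. Il1b was 1.81-fold (log2 0.85 ± 0.25, higher in 4 of 4 donors), with an adjusted p of 0.162 and, with the block, 0.0051, and Il1rn (1.02-fold), Tnf (0.982-fold), Nfkbia (1.16-fold) and Mx1 (1.03-fold) did not pass (adjusted p = 0.489 to 0.955).

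In limma 27 probe sets of 18 genes passed with autologous plasma, 25 higher and 2 lower (adjusted p = 0.0026 for Ciita, 0.00096 for Rasd1 and 0.0406 for Rab27b). With the donor as a block 3907 passed, 1423 higher and 2484 lower. By the same rule, applied after the result was seen, the largest blocked rises beside that of Rab27b were those of Kcnab1, a potassium channel subunit gene (3.07-fold), Serpinb6a (2.37-fold), Clec1b, a platelet lectin receptor gene (2.37-fold), Gng11 (2.36-fold), Mmrn1, which encodes multimerin of platelets and endothelium (2.34-fold), Alox12, the platelet 12-lipoxygenase gene (2.32-fold), and F13a1, which encodes coagulation factor XIII (2.30-fold), with blocked adjusted p between 3.5e-05 and 0.00048. The largest blocked falls after Ciita were those of the transcriptional regulator gene Spen (0.490-fold), the class II gene RT1-Bb (0.510-fold), Hcfc1 (0.522-fold), the T-cell transcription factor gene Tcf7 (0.527-fold) and Bcor (0.535-fold), with Bcl6 (0.563-fold) and Bcl3 (0.569-fold) further down. Under quantile normalization the calls without the block were 77, 49 higher and 28 lower, and with only the 8 arrays of these groups they were 0. Without donors 1, 2, 3 and 4 the count of 27 became 1600, 1, 0 and 3, and the blocked count 1699, 1749 and 1512 without donors 2, 3 and 4. Without the autologous array of donor 1 the count of 27 became 2209, without those of donors 3 and 4 it was 5 and 10, without the DR ND arrays of donors 1, 2, 3 and 4 it was 15, 3, 3 and 66. The blocked count became 1662 without the autologous array of donor 3 and 2236 without the DR ND array of donor 2 and 2415 without that of donor 3.

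Of the 24 lists, 4 passed with autologous plasma by camera. The platelet list had a median of 0.95 (adjusted p = 9.2e-07, but adjusted p = 0.47 with an estimated correlation and 0.29 with the block too). All 8 tested members rose with the block, among them Clec1b (log2 1.24 ± 0.14), the chemokine gene Ppbp (1.06 ± 0.17), Treml1 (1.05 ± 0.14) and Pf4, platelet factor 4 (0.73 ± 0.11). Without the block 0 passed over all probe sets and 8 adjusted over the list alone. With DR HCD, DR B/S and F+/+ plasma the platelet medians against DR ND were -0.05, 0.04 and 0.07. MHC class II presentation was lower, with a median of -0.30 (adjusted p = 0.00035, and adjusted p = 0.47 with an estimated correlation and 0.29 with the block too). Of its 9 tested genes only Ciita passed without the block (4 lower and 1 higher adjusted over the list alone). With the block 6 fell (Ciita, RT1-Bb, RT1-DMa, RT1-DMb, the invariant chain gene Cd74 and RT1-Da) and 1, the co-stimulatory gene Cd86 (log2 0.63 ± 0.12), rose (8 and 1 adjusted over the list alone). Of the 12 monocyte and macrophage genes 0 passed without the block (4 adjusted over the list alone) and 6 rose with it, Lyz2, Fcer1g, Cd14, Ctss, Csf1r and Tyrobp, with a list median of 0.21 (adjusted p = 0.010, and 0.47 with an estimated correlation). Donor 1 stood apart. The mean centred log2 value of this list was -0.15 on its autologous array, against 0.12 to 0.13 on the others. Its Lyz2 value was 8.01 with autologous and 8.01 with DR ND plasma. The list of IL-1 and innate inflammation, with a median of 0.14, passed without the block (adjusted p = 0.041, and adjusted p = 0.47 with an estimated correlation) and not with it (adjusted p = 0.117), where Il1b and Il18, at log2 0.85 ± 0.20 and 0.64 ± 0.11, rose (2 adjusted over the list alone in either fit).

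**Figure D2:**
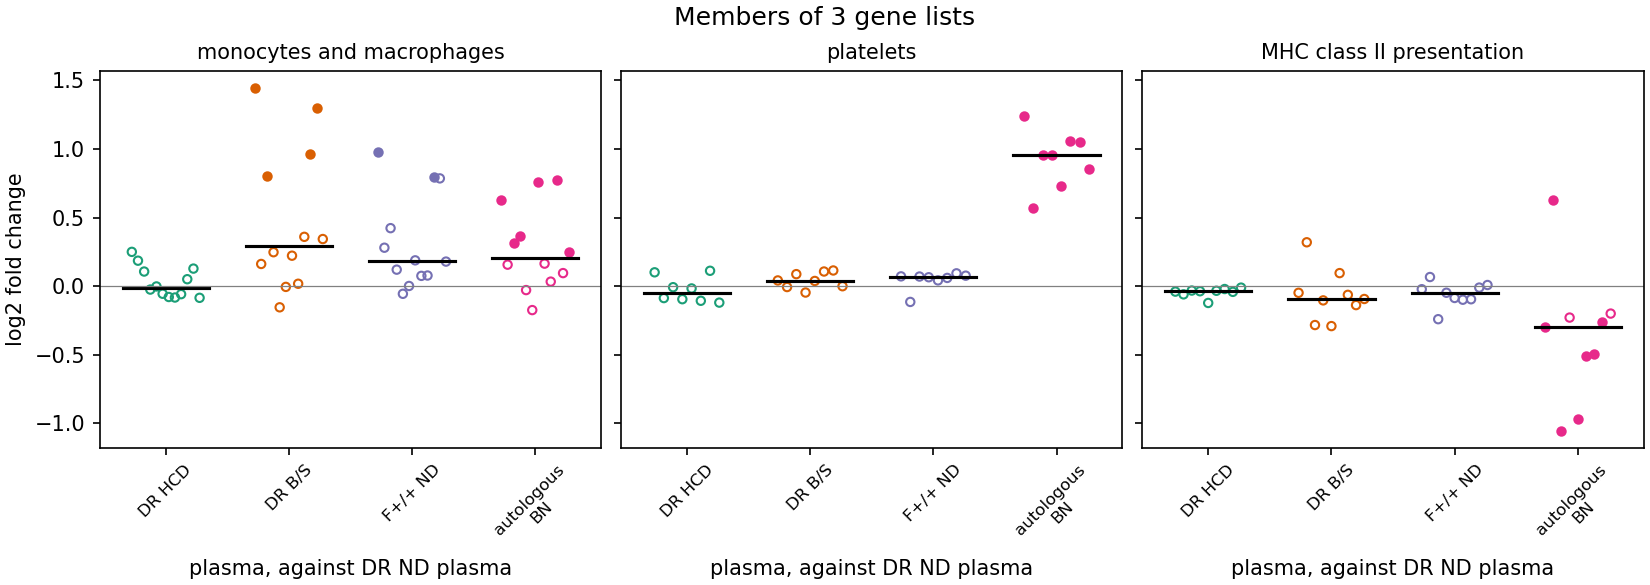
Log2 fold changes of the tested members of 3 gene lists against DR ND plasma, by plasma (circles, genes, filled where the blocked adjusted p was under 0.05; bar, median). The platelet median was 0.95 with autologous plasma and between -0.05 and 0.07 with the other plasmas.

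The plasmas of the diet and the antibiotics were compared directly, which also tests whether their effects against DR ND differed. With DR HCD plasma Fn1 was 3.74-fold lower than with DR B/S plasma (log2 -1.90 ± 0.24 SE, n = 4 arrays per group), Tgfbi 3.19-fold (log2 -1.67 ± 0.15), Vcan 3.15-fold (log2 -1.65 ± 0.23), Ccr1 3.08-fold (log2 -1.62 ± 0.20) and Gpnmb 2.47-fold lower (log2 -1.30 ± 0.21), each in 4 of 4 donors. In limma 17 probe sets passed, 0 higher and 17 lower, with a Benjamini-Hochberg adjusted p of 4.1e-06 for Tgfbi and 0.00027 for Fn1. With the block 81 passed, 5 higher and 76 lower, and the early response gene Gadd45g (1.45-fold) and H1f2 (1.45-fold) were the named genes higher with DR HCD plasma. By camera 7 lists were lower: monocytes and macrophages (median -0.36, adjusted p = 4.8e-09), SREBP (-0.19), unfolded protein stress (-0.19), NF-kappaB (-0.14), NRF2 (-0.13), PPAR (-0.13) and hypoxia (-0.12). With an estimated correlation the adjusted p was 0.056 for monocytes and macrophages and 0.23 to 0.50 for the others. Of the 12 monocyte and macrophage genes 3 fell (Cd14, Mpeg1 and Csf1r; 5 adjusted over the list alone), and 5 fell with the block (8 adjusted over the list alone). The count of 17 came down to 5 without donor 3 or 4, to 11 without the DR HCD array of donor 2 or 3 or the DR B/S array of donor 4 and to 10 without the DR B/S array of donor 3. The blocked count of 81 came down to 52, 44, 39 and 33 without donors 1 to 4, to 39 without the DR HCD array of donor 3, 53 without that of donor 4, and 50 and 39 without the DR B/S arrays of donors 2 and 3.

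DR HCD and F+/+ plasma were compared directly as well. By limma 0 probe sets passed without the block (165 at an unadjusted p under 0.05) and 14 with it (1 higher, 13 lower), so the genes named come from the blocked calls. Fn1 (2.45-fold lower, blocked adjusted p = 5.5e-05), Vcan (2.07-fold, 0.0112), Slpi, a protease inhibitor gene (1.96-fold, 0.0112), Clec4a3 (1.83-fold, 0.0056) and Tgfbi (1.78-fold, 0.0112) were lower and Abcg1 was 1.63-fold higher (0.0058). Mylip, filled by unadjusted p, was 1.41-fold and did not pass (0.124), nor did Dnai7, Hpgds and Zfyve28. By camera 9 lists differed. The LXR list was higher (median 0.10, adjusted p = 0.00048, and adjusted p = 0.095 with an estimated correlation, 0.017 with the block too), with Abcg1 at log2 0.70 and Mylip at 0.50. Of its 7 members 0 passed without the block and 1, Abcg1, with it (2 adjusted over the list alone in either fit). Lower were monocytes and macrophages (median -0.21, adjusted p = 3.5e-10, and adjusted p = 0.035 with an estimated correlation), the glucocorticoid list (-0.17, with adjusted p = 0.28 by an estimated correlation and 0.017 with the block too), and SREBP (-0.14, with 0.24 and 0.041). Unfolded protein stress, NRF2, PPAR, hypoxia and NF-kappaB were also lower (medians -0.11 to -0.07), with adjusted p of 0.25 to 0.41 with an estimated correlation. Of the 12 monocyte and macrophage genes 0 passed in either fit (3 fell adjusted over the list alone, 5 with the block). The blocked count of 14 was 7 and 3 without donors 3 and 4, 9 and 8 without the DR HCD arrays of donors 3 and 4 and 4 without the F+/+ array of donor 1. Without donor 2 or its F+/+ array the unblocked count was 2 or 3.

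Between DR B/S and F+/+ plasma, Ubd was 2.02-fold higher with DR B/S plasma (log2 1.02 ± 0.11 blocked SE, n = 4 arrays per group), Lgals3 1.83-fold, Tgfbi 1.79-fold and Ccr1 1.77-fold higher, and Rasd1 was 1.71-fold and the glucocorticoid-induced chaperone gene Fkbp5 1.47-fold lower, with Gadd45g (1.42-fold), Cdyl2 (1.42-fold) and H1f2 (1.36-fold) also lower. These passed with the donor as a block (limma adjusted p = 0.00012 for Ubd, 0.0047 for Fkbp5), where 10 probe sets passed, 4 higher and 6 lower. Without the block 0 passed (388 at an unadjusted p under 0.05). Nqo1, filled by unadjusted p, was 1.46-fold higher and did not pass (blocked adjusted p = 0.15). By camera 5 lists differed: the glucocorticoid list was lower (median -0.12, adjusted p = 0.0017), and LXR (0.13, 0.0017), proliferation (0.12, 0.0017), monocytes and macrophages (0.15, 0.026, and 0.060 with the block) and unfolded protein stress (0.11, 0.036) were higher. With an estimated correlation the adjusted p were 0.46 (0.021 with the block too), 0.14 (0.021), 0.033 (0.13), 0.74 and 0.80. The blocked count was 5, 1, 1 and 2 without donors 1 to 4, 16 without the DR HCD array of donor 3 and 3 to 5 when the DR B/S array of donor 2, 3 or 4 or any F+/+ array was left out.

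Of the 24 tested lists 11 passed in none of the 7 comparisons with or without the block, with a smallest adjusted p of 0.108 and medians from -0.09 to 0.13. These were T cells, B cells, NK and cytotoxic cells, erythroid cells, chemokines, type I interferon response, regulatory and anti-inflammatory genes, aryl hydrocarbon receptor targets, heat shock, immediate early genes, and p53 and apoptosis. The T-cell list had a median of 0.02 with DR B/S and autologous plasma and -0.01 with DR HCD and F+/+ plasma. The lists too small to test had 2 tested neutrophil genes, 2 dendritic cell genes and 3 plasma cell genes. Their medians with autologous plasma were 0.21, -0.01 and -0.27, and with DR B/S plasma 0.10, -0.13 and -0.12.

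The rises with DR B/S and F+/+ plasma involved shared genes, and because all were measured against the same DR ND arrays the overlap was set beside what shared controls give. With the block 16 probe sets rose with both, among them Fn1, Ccr1, Cd14, Clec4a3, Gpnmb, Tgfbi, Lyz2, Ier3 and Ninj1. For independent lists 0.072 were expected, but the shared arrays break that independence, here and for the expected numbers below. Simulated unchanged groups shared 0, but groups without a change have few calls to share. Neither value therefore tests the overlap. When each comparison had its own 2 of the 4 DR ND arrays, 6 to 10 calls were shared. The F+/+ comparison itself had only 6 to 10 calls in these splits. With the DR ND arrays of donors 1 and 3 for DR B/S, 6 of its 9 were shared, and in the other splits all were. The fold changes correlated with r = 0.49 across probe sets, which are not independent replicates. Simulated unchanged groups gave a mean r of 0.46 and a highest of 0.94, and the split controls a mean r of 0.08. The covariance of 0.00687 exceeded the simulated mean by 0.00123 and lay below the simulated highest of 0.0184. Between DR B/S and autologous plasma 42 probe sets rose with both and 1 moved in opposite directions (6.44 shared in 1 direction expected, 8 to 20 with split controls, where DR B/S had 26 to 58 calls). Between F+/+ and autologous plasma 14 rose and 1 fell with both (1.43 expected, 3 to 5 with split controls, where F+/+ had 6 to 10 calls). The r was 0.24 for DR B/S and autologous plasma and 0.11 for F+/+ and autologous plasma. The means were 0.48 and 0.46 simulated and 0.09 and -0.09 with split controls. The covariances, 0.00846 and 0.00265, differed from the simulated means by 0.00262 and -0.00294 and lay below the simulated highest, 0.0158 and 0.0192. DR HCD plasma shared 0 calls with the others, having none. Its fold changes correlated with those of DR B/S, F+/+ and autologous plasma with r of 0.24, 0.36 and 0.04, below the simulated means of 0.46, 0.47 and 0.48. With split controls these were -0.12, -0.16 and -0.16, and the covariance differences were -0.00245, -0.00228 and -0.00462. The lowest simulated values were not kept, so whether values below the simulated means lie outside the simulated spread cannot be told.

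The 20 arrays separated mainly by responder donor. The first principal component held 43.6% of the variance and the second 23.7%. The autologous arrays of donors 2, 3 and 4 had the highest values on the first component, while that of donor 1 lay beside the other arrays of its donor.

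**Figure D3:**
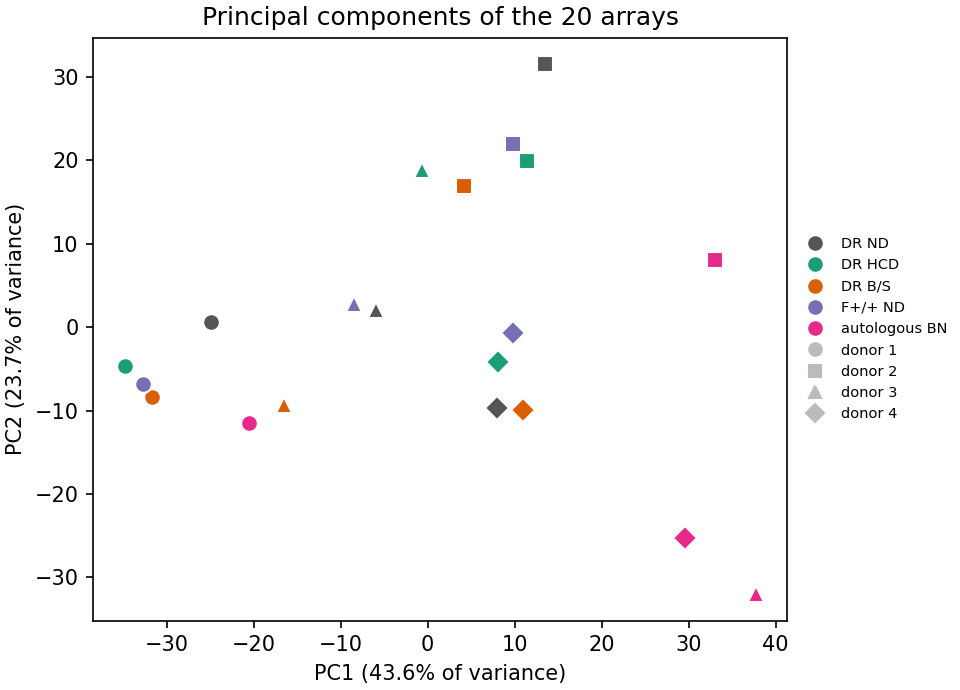
The first 2 principal components of the 20 arrays (colour, plasma; symbol shape, responder donor). Arrays of donors 1 and 2 lie apart from each other, and the autologous arrays of donors 3 and 4 lie at the lower right.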

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

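Of the tests in this part, only those of array and RNA quality against the full sets of calls were set before their result was seen (though not how far a correction had to move the probe sets to count), and the others, the splits of the samples included, were chosen afterwards.

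Of 90 sets of 4 values tested, 4 held a sample far from the other 3, where chance gives about 1 in 20 (5%). The hybridisation spikes of the DR HCD array of donor 3 were 11.6 (log2), against 10.2 to 10.3 on the other DR HCD arrays. The GAPDH 3' minus 5' difference of the DR ND array of donor 3 was 0.290, against 0.010 to 0.041. The monocyte and macrophage score, the mean centred log2 value of the list, was -0.15 for the autologous array of donor 1, against 0.12 to 0.13. The same score was -0.36 for the DR ND array of donor 2, against -0.18 to -0.17.

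The genes raised by DR B/S plasma may reflect a response of the responder cells to that plasma. Of the 13 genes called without the block 3 were among the 12 of the monocyte and macrophage list, out of 10162 tested genes. With the block 4 were. The list is short, so this overlap does not tell which cells express the other raised genes. A larger share of monocytes as the whole cause cannot be told apart from the plasma. The 20 probe sets called without the block had a median log2 change of 1.38, against the monocyte list's 0.30 (member SD 0.53). They were called on this same change, with none below 0.80, and the list was not, so these medians decide nothing. The 79 raised with the block had a median of 0.63, within that SD. DR ND arrays out of place as the whole cause were argued against by the comparison of DR HCD with DR B/S plasma. Its fold changes do not use the DR ND arrays. Over all tested probe sets it called 76 lower with DR HCD plasma in the blocked fit, and 56 of these were among the 79. The 79 were chosen partly for high values on the DR B/S arrays, which that comparison shares, so the 56 alone decide nothing. With 4 measures of array and RNA quality added to the blocked model all 20 calls made without the block passed. None of these changes was below 0.80, while the measures moved a probe set by a median of 0.058, so this is a weak test of quality. Of the 79 only 31 passed. Their median change went from 0.63 to 0.62 over the 79, while its SE rose from 0.106 to 0.128 with 8 residual degrees of freedom. For the other probe sets quality cannot be told apart from the plasma. A rise in monocyte share, and differences between the plasmas that the antibiotics did not cause, stay open.

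The change with autologous plasma may hold more than 1 component. All 8 tested platelet markers were raised, which is consistent with platelets or their RNA in the autologous cultures. Dilution by platelet RNA would shift all transcripts that platelets do not add to by the same amount. Of the 2484 called falls 328 reached 1.5-fold. The median log2 changes of the T-cell and B-cell lists were no lower than -0.05 and -0.085 in any comparison. The median of all tested probe sets was -0.0056 with autologous plasma. A shared shift of that size stays short of 1.5-fold, which argues against dilution as the whole cause of these 328 falls. They are the largest falls, and for the smaller ones dilution cannot be told apart from the plasma. With the 4 quality measures in the blocked model 3388 of 3907 calls passed, but the measures moved only 1.05% of the probe sets by more than their SE (26.0% for DR B/S plasma), so array or RNA quality cannot be told apart from the plasma. Strain, age and self against non-self plasma, which the design joins, stay open and were not tested.

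After the group means were removed, 3 of the 20 arrays, all of donor 3, had a higher mean correlation with another donor than with their own. The other arrays of donor 3 had own-donor correlations of only 0.178 and 0.175. With the group means left in, the DR B/S and DR HCD arrays of donor 3 correlated best with its F+/+ array (0.992 and 0.988) and next with its DR ND array (0.992 and 0.986). The autologous array of donor 3 then correlated best with that of donor 4 (0.989). Cells of another of the 4 responder donors were argued against for the DR HCD array (0.27 with donor 2, -0.06 with its own) and the DR B/S array (0.31 with donor 1, 0.15 with its own), which lay below 0.40, the lowest own-donor value among donors 1, 2 and 4 (SD 0.11), with erythroid scores of -0.32 and -0.30 outside the ranges of those donors, 0.38 to 0.57 and -0.57 to -0.42. For the autologous array of donor 3 the measures disagreed and cells of donor 4 cannot be told apart from those of donor 3, since it correlated with donor 4 at 0.55 and with its own donor at 0.04, while its erythroid score of -0.25 was within donor 3's -0.32 to -0.17 and below donor 4's 0.07 to 0.47. If the label were wrong, the donor block would pair this array wrongly, and without it 1662 probe sets passed with the block in place of 3907. The hybridisation spikes of the DR HCD array lay 0.85 above the highest other array and its labelling spikes, 9.02, within the others' 8.71 to 10.4, which is consistent with less sample RNA on this array, and no biological explanation was tested.

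The 8 arrays of each pair of groups can be split into 4 and 4 in 35 ways, of which only 8 part all donor pairs as the real split does, too few for a share under 0.05. Without the block, as many probe sets as in the real split were called in 1 of the 35 splits for DR B/S against DR ND (20 called, highest other 0), F+/+ ND against DR ND (2, highest other 0) and DR HCD against DR B/S (17, highest other 0). The other 27 of the 35 splits keep some donor pairs together. For the counts of 0, DR HCD against DR ND, DR HCD against F+/+ ND and DR B/S against F+/+ ND, each of the 35 splits had to give as many (highest other 0), so the splits decide nothing. For autologous against DR ND plasma 2 of 35 splits gave as many as the real 27. The other of these called 2654 probe sets and set the autologous array of donor 1 with the DR ND arrays of donors 1 to 3, which points to a structure of the samples, and among the 8 splits that part all pairs the highest other was 0.

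With the block, 8 splits part all donor pairs, too few for a share under 0.05. The real count and the highest other were 82 and 0 for DR B/S, 18 and 0 for F+/+ ND and 3907 and 1 for autologous plasma against DR ND. They were 14 and 0 for DR HCD and 10 and 0 for DR B/S against F+/+ ND, and 81 and 0 for DR HCD against DR B/S, and in each of these 1 of 8 splits gave as many. For DR HCD against DR ND the count was 0, so all 8 splits had to give as many.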

How the results depend on the processing

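The alternatives chosen after seeing the data were the block with only the arrays of the 2 groups, the fits without the DR HCD array of donor 3 for the lists and for the comparisons that do not use DR HCD plasma, the changes of filter, scaling, variance model, threshold and arrays made to the blocked fit, the block with an estimated correlation for the lists, and the settings of the genes named in the 3 comparisons not against DR ND. None of the genes named in the 7 comparisons that passed the threshold changed sign under the 2 scalings. The block and the lack of a filter leave each fold change as it is, and these genes had the same sign in all 4 donors. Their signs could therefore not change with the block, without the filter or without a donor. Of the 6 similarities 4 changed sign with the DR ND arrays split, and that of DR HCD with autologous plasma also did without donor 2. The cause was not tested for the changes below.

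With the donor as a replicate block the counts were 82 (not 20) for DR B/S, 18 (not 2) for F+/+ ND and 3907 (not 27) for autologous against DR ND plasma, 14 (not 0) for DR HCD and 10 (not 0) for DR B/S against F+/+ ND, and 81 (not 17) for DR HCD against DR B/S. As a random replicate block they were 81, 18, 3531, 14, 8 and 88, and with the replicate block and only the 2 groups 78, 31, 1695, 22, 1 and 39, in the same order. The replicate block also brought 26 of the 108 genes named in the 7 comparisons past the threshold, took the lists from 4 to 3 for autologous against DR ND and from 5 to 4 for DR B/S against F+/+ ND, and changed no other call of a named gene or a list.

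Without the block, array weights gave 33 for DR B/S, 18 for F+/+ ND and 5399 for autologous against DR ND, 9 for DR HCD and 3 for DR B/S against F+/+ ND, and 40 for DR HCD against DR B/S. The unmoderated linear model gave 13, 0 and 4 against DR ND and 10 for DR HCD against DR B/S. The stricter filter gave 9 for DR B/S, 0 for F+/+ ND and 7 for DR HCD against DR B/S. Quantile normalization gave 1 for F+/+ ND and 77 for autologous plasma, and median centring 1 and 17. With 1 probe set per gene F+/+ ND had 1. With only the 2 groups F+/+ ND had 1, autologous plasma 0, and DR HCD against F+/+ ND 1, which limma-trend with robust moderation also gave.

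In the blocked fit, a minimum of 1.5-fold left 45 for DR B/S and 518 for autologous against DR ND, 5 for DR B/S against F+/+ ND and 44 for DR HCD against DR B/S. The stricter filter gave 10 for F+/+ ND against DR ND, 5 for DR HCD against F+/+ ND and 53 for DR HCD against DR B/S. Limma-trend with robust moderation gave 18 for DR B/S against F+/+ ND.

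With an estimated correlation the lists past the threshold went from 6 to 1 for DR B/S, 9 to 1 for F+/+ ND and 4 to 0 for autologous against DR ND, from 9 to 1 for DR HCD and 5 to 1 for DR B/S against F+/+ ND, and from 7 to 0 for DR HCD against DR B/S. With the replicate block as well they were 0, 2, 0, 4, 2 and 0. With the DR ND arrays split, the similarities of DR HCD to DR B/S, F+/+ ND and autologous plasma were -0.12, -0.16 and -0.16, of DR B/S to F+/+ ND and autologous 0.0797 and 0.0856, and of F+/+ ND to autologous -0.0855.

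Leaving out donors or arrays, the counts without and with the replicate block ranged from 0 to 0 and 0 to 0 for DR HCD, 6 to 21 and 38 to 102 for DR B/S, 0 to 5 and 7 to 21 for F+/+ ND, and 0 to 2209 and 1512 to 5085 for autologous against DR ND. They ranged from 0 to 3 and 3 to 16 for DR HCD and 0 to 0 and 1 to 16 for DR B/S against F+/+ ND, and from 5 to 21 and 33 to 74 for DR HCD against DR B/S. The lists ranged from 0 to 1, 6 to 7, 6 to 9 and 2 to 4 against DR ND, 5 to 13 and 3 to 5 against F+/+ ND, and 6 to 9. The similarities ranged from 0.0885 to 0.53, 0.35 to 0.45 and -0.12 to 0.28 for DR HCD with DR B/S, F+/+ ND and autologous plasma, 0.35 to 0.61 and 0.21 to 0.38 for DR B/S with F+/+ ND and autologous, and 0.0185 to 0.24 for F+/+ ND with autologous.

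For the genes named in the 7 comparisons, 67 of 232 alternatives of calls past the threshold lost the call and 29 of 632 of the others gained it.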

Other observations

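The values in this part were picked out after the results were seen.

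With autologous plasma some lists that did not pass as a set held members that passed with the donor as a block. In this fit 3907 of all 18625 probe sets passed, so some members of any list are likely to pass. Among the 17 tested T-cell genes the transcription factor genes Tcf7 (log2 -0.92 ± 0.16 SE), Bcl11b (-0.76 ± 0.18) and Lef1 (-0.56 ± 0.11) and the kinase gene Lck (-0.23 ± 0.08) fell. The T-cell surface genes Cd3e, Cd4 and Cd8a were at 0.02, 0.08 and 0.03 and did not pass. Among the 11 tested chemokine genes Cxcl2 (0.72 ± 0.19), Ccl6 (0.59 ± 0.11), Ccl4 (0.31 ± 0.09) and Ccl5 (0.25 ± 0.08) rose. Of the 26 type I interferon genes 5 rose, among them Gbp2 (0.56 ± 0.11), Ifi44 (0.41 ± 0.10) and Isg15 (0.36 ± 0.09), and 1, Irgm (-0.26 ± 0.08), fell.

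Scores of 2 cell type lists are given by responder donor, without a test. The erythroid score averaged -0.47 ± 0.06 (SD over the 5 cultures), 0.51 ± 0.07, -0.25 ± 0.06 and 0.21 ± 0.17 in donors 1 to 4, and the B-cell score 0.25 ± 0.06, -0.16 ± 0.06, -0.12 ± 0.05 and 0.03 ± 0.04. In the autologous cultures the platelet score was 0.12, 0.52, 1.3 and 0.97 in donors 1 to 4.

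Of the 79 probe sets raised by DR B/S plasma with the block, with a median log2 change of 0.63, 78 were also above their DR ND mean with F+/+ plasma (median 0.32), 68 with autologous plasma (0.30) and 60 with DR HCD plasma (0.08). These comparisons share the DR ND arrays, so part of this may come from those arrays. With 2 of the 4 DR ND arrays for each comparison the correlation of DR B/S with F+/+ fold changes went from 0.49 to 0.0797. That correlation is over all tested probe sets and not over the 79.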
